A study of Mus musculus with 20 samples.

How the data were processed

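The files are the scanner output of 20 two-colour Agilent arrays and one table of values for the series. Per the labels, each array holds tail DNA of 1 mouse of the family in one channel and DNA of 1 reference male in the other, and the dyes were exchanged between the 2 arrays of a mouse. Per the file headers, the arrays were read with Feature Extraction 10.7.1.1 under protocol CGH_107_Sep09, with probe positions of the mm9 build. The deposited processed intensities are, per the file headers, background-subtracted, spatially detrended and dye-normalized with a linear factor per channel. The deposited log10 ratio of each spot is, per the file headers, that of the red over the green processed signal; on every array at least 99.97% of spots lay within 0.01 of the ratio computed from those signals. The values in the deposited table of the authors are log2 ratios of reference over mouse: each column equalled the array's own log ratio within 0.0117 after its sign was turned by the dye, with column medians between -0.0041 and 0.0105, so its scale, centring and direction were settled by that comparison. How the table was made is not given in the sources used here.

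Each array had 159315 spots of probes and 6563 control spots. Control spots were left out, as were 107 to 204 spots per array with an outlier flag; 203 to 726 spots per array were not well above background in both channels, and none was saturated. Spots of the same probe were averaged. The log2 ratio of processed signals was turned to mouse over reference by the dye in the labels, and each array was centred on its autosomal median, with no loess or quantile step, since a copy number array carries true shifts. Both orientations of a mouse were averaged and count as 1 replicate. Progeny are separate animals of 1 family, and p-values over them say nothing of other families. Parents lay on slide 1 and progeny on slides 2 to 5, so that generation and slide are tied.

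Aberrant regions were called per mouse with an interval score, the sum of ratios over the noise SD divided by the root of the number of probes. The noise SD came from differences of neighbouring probes and was 0.0423 to 0.0665. A stretch was called at a score of 6, at least 3 probes, a mean absolute log2 ratio of 0.25 and at least 0.125 in each orientation, and it could not cross a gap of 50 kb or hold over 5000 probes. Calls of the same sign that overlapped by 1 bp were merged across mice, and the core of a region is the stretch covered by most mice. A mouse carries a region when its mean over the core passes the limits of size. A region is progeny-only when neither parent carries it and a carrier lies 0.25 or more from both parents. For false calls, the caller was run on the difference between orientations after removal of its median over mice and without the rule on orientations. Regions of 1 parent were tested for even transmission to 8 progeny with a two-sided exact binomial test, and calls per mouse with a two-sided exact permutation test over 45 splits. Per probe, limma fitted father, mother and progeny on the 10 mouse means with Benjamini-Hochberg adjustment at 0.05. X and Y probes were kept out of calls and fits and reported on their own.

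Named regions follow a rule fixed before the data were examined: of each class, the 6 with the highest absolute mean over carriers and the 4 with most probes, with all of a class of 6 or fewer, and for limma the 5 probes with the largest change in each direction; few of these stand in the text and the rest are summarised by class. The 25 regions from calls of 10 or more probes were singled out after their values were seen. The files pair no gene with a probe and the gene table at hand is of another build, so regions are given by position only, and the 15 gene lists fixed beforehand were not tested.

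Alternatives fixed before the data were examined were normexp on the median spot and background signals (offset 50; the mean signals that normally enter it are not used here), loess within array (span 0.3), the value table, each probe less its median over the mice, scores of 8 and 5, the latter of which changed no call, at least 5 probes, a log2 ratio of 0.4, a gap of 500 kb, merging at 50% reciprocal overlap, no rule on orientations, each orientation alone, only the 154332 probes well above background in both channels of all arrays, slide as a random block, runs of 10 neighbouring probes, and leaving out each progeny mouse. Others were added after seeing the data: 10 or more probes, as a filter on calls or in the caller, a median rule, leaving out progeny 6 and 8 together, removal of the first principal component of the variation between mice, and removal of medians by probe length (45 to 60 bases).

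The caller was tested on simulated data with the real probe layout and noise of each mouse. For aberrant regions over 155230 probes, it found 86% of 200 stretches of 3 probes at 0.3 and 100% at 0.45, and 100% of 200 stretches of 10 probes at 0.3, with 0 calls outside them in independent noise. The arrays gave 316 false calls, so that the simulated noise does not stand for all noise of the arrays; whether noise is shared between neighbouring probes or has heavy tails was not tested. For limma on 20000 simulated probes, all 67 probes changed by 0.3 were recovered for progeny against parents and 32 of 67 for father against mother. Of 67 probes changed by 0.1, 6 were recovered for progeny against parents and 0 for father against mother. These simulated probes had independent noise of the same SD in every mouse and at every probe. The mice of the arrays were correlated across probes, so that recovery on the arrays may differ. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and data.table in version 1.17.8.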

Results

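DNA copy number was measured in 1 family of C57BL/6JNrs mice, an inbred strain, with tail DNA of a father, a mother and their 8 progeny. Each mouse was compared by array comparative genomic hybridisation, in which test and reference DNA compete for the same probes, with DNA of 1 reference male from the same colony. Every mouse was hybridised on 2 arrays with the dyes exchanged, giving 20 arrays on 5 slides of 2 mice each. The array was a secondary screen: its 155281 probes tile regions picked because a first array had shown an aberration at them, so counts of regions are not rates over the genome, and the picks are not independent of earlier data on the mice of this family. The probes had a median spacing of 82 bp within their clusters, and 155230 of them lie on autosomes in the mm9 build. Median signals were between 13.8 and 23.9 times the local background in each channel. The precision is limited by the number of arrays, which is 2 per mouse and 1 family in all. Log2 ratios are mouse over reference throughout, a value of a mouse is the mean of both dye orientations, and a ± after the value of 1 mouse is the deviation of either orientation from that mean.

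The series asks whether male mice kept under gamma rays at 1 mGy per day for 400 days pass copy number changes to their progeny. The name of this family carries that dose, while the design text calls its male not irradiated. The exposure of the father is therefore not settled here, and no irradiated family was set against an unexposed one. What the family can show is which regions the progeny carry that neither parent shows, and which regions came from a parent.

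How many of the long regions were carried by a parent depended on how long regions were called. Of the 25 regions that rest on called stretches of 10 or more probes, 14 were carried by 1 parent and by progeny, 3 by all 10 mice and 2 by both parents and some of the progeny. Another 2 were carried by progeny and by neither parent, and 4 by progeny whose values did not separate from those of a parent. Neither of these 2 progeny-only regions was longer than 10 probes. The limit of 10 probes was chosen after the values were seen, and it was applied to the calls of 3 or more probes. The same filter left 0 false calls, which are calls on differences between dye orientations, in which copy number cancels. Any other signal that both orientations of a mouse share cancels there as well, so false calls count only what differs between orientations. Progeny 6, with 886 calls of 3 or more probes, had 20 false calls. When the caller itself was run with at least 10 probes, it returned 90 regions, with 3 false calls. Of the 90, 21 were carried by 1 parent, 3 by both parents, 3 by all 10 mice and 19 by progeny only. The rest were carried by progeny whose values did not separate from those of a parent, or had no carrier over their core. The 25 regions of the filter are described below.

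**Figure D1:**
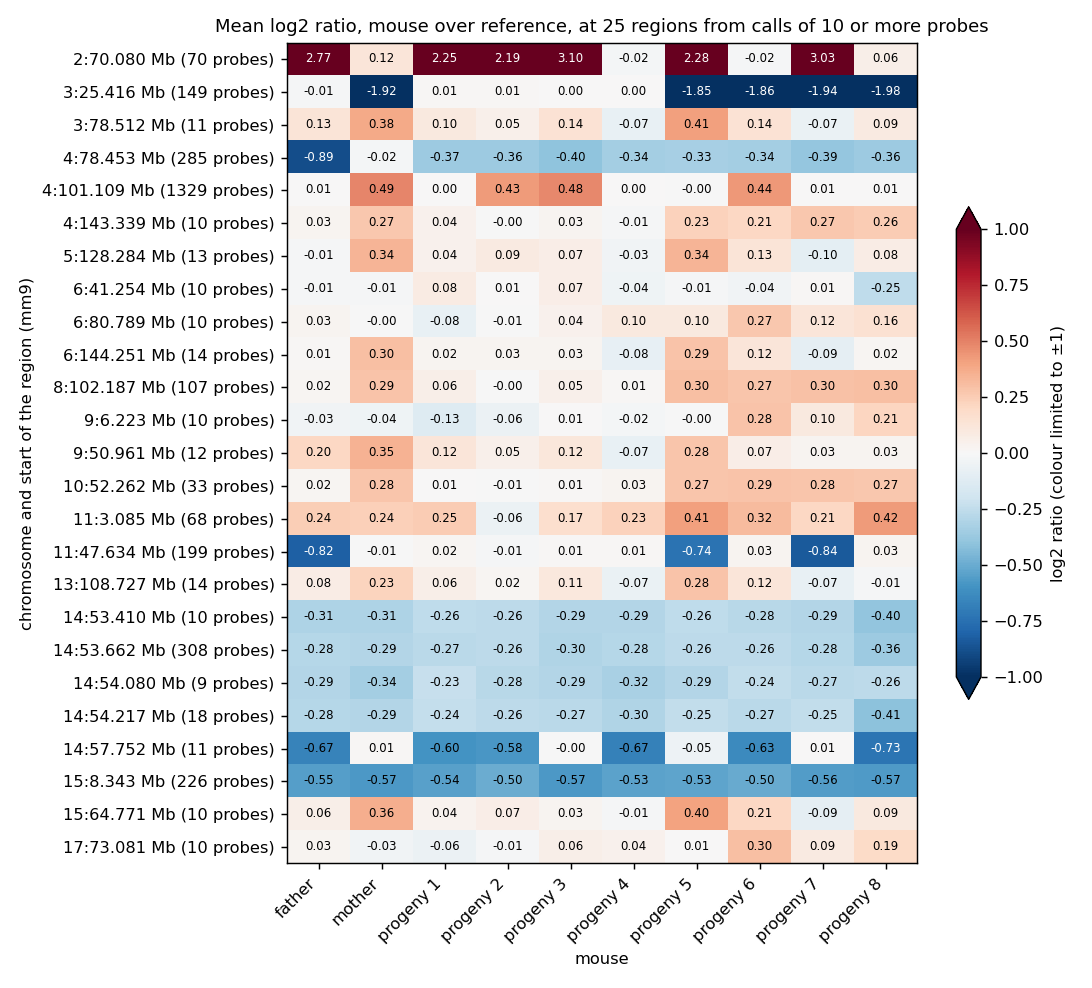
Mean log2 ratio, mouse over reference, of each of the 10 mice (columns) at the 25 regions that rest on called stretches of 10 or more probes (rows, by chromosome and start in mm9, with the number of probes). Red is above 0 and blue below, with the colour limited to ±1 and the value printed in each cell; the loss on chromosome 4 from 78452572 is -0.89 in the father and between -0.40 and -0.33 in the 8 progeny.

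The father and not the mother carried 4 of these regions, and some or all of the progeny carried each of them. On chromosome 4, a loss of 57.5 kb over 285 probes (78452572 to 78510061) measured -0.89 ± 0.06 in the father and -0.02 ± 0.02 in the mother. All 8 progeny lay between them at -0.36 ± 0.02 (SD, n = 8). The midpoint of the parents' linear ratios of 0.541 and 0.989 is -0.39 on the log2 scale, and the progeny mean differed from it by 0.03. On chromosome 11, a loss of 26.8 kb over 199 probes (47634227 to 47661054) measured -0.82 ± 0.02 in the father, -0.74 ± 0.01 in progeny 5 and -0.84 ± 0.00 in progeny 7, while the other 7 mice lay between -0.01 and 0.03. On chromosome 14, a loss of 1.27 kb over 11 probes (57751960 to 57753226) measured -0.67 ± 0.13 in the father and between -0.73 and -0.58 in progeny 1, 2, 4, 6 and 8.

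On chromosome 2, a gain of 7.27 kb over 70 probes (70079530 to 70086801) had the largest ratios of the 25 regions. It was carried by the father, at 2.77 ± 0.03, and by progeny 1, 2, 3, 5 and 7, at 2.19 to 3.10. The mother and progeny 4, 6 and 8 lay between -0.02 and 0.12. The reference gave little signal there. Between 58.6% and 75% of its spots at these probes were well above background, against 99.4% of all probes of the array that were so on every array in both channels. The ratios are lower bounds for that reason, and the 6 carriers had at least 4.55-fold more signal than the reference. In the mouse channel alone, the 6 carriers lay between -0.65 and -0.48 relative to each array's autosomal median, and the 4 other mice between -3.85 and -2.89. With all called stretches of 3 or more probes, the shared core of this region shrank to 3 probes, where the mother's 0.26 and progeny 8's 0.35 counted as carried, so that the region fell under both parents. In the same way, the cores of the chromosome 11 loss and of the long maternal gain on chromosome 4 shrank to 3 probes, at which progeny 6 and 8 and progeny 4 also counted as carriers.

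**Figure D2:**
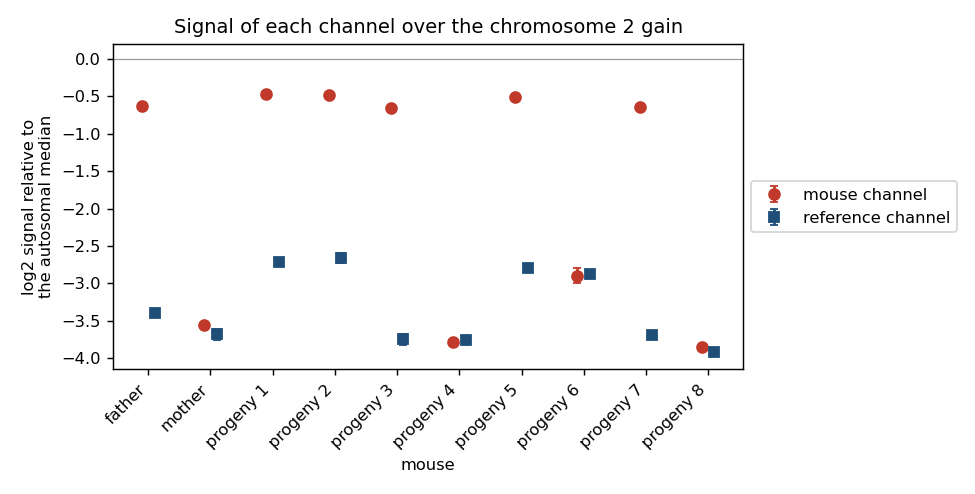
Log2 signal over the 70 probes of the chromosome 2 gain relative to each array's autosomal median, for the mouse channel (red circles) and the reference channel (blue squares) of each of the 10 mice; bars are the deviation of either dye orientation from the mean. The father and progeny 1, 2, 3, 5 and 7 sit between -0.65 and -0.48 in the mouse channel, while the reference channel lies between -3.92 and -2.66.

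The mother and not the father carried 10 of the 25 regions. The region with most probes was a gain of 162 kb over 1329 probes on chromosome 4 (101109089 to 101270967), which measured 0.49 ± 0.01 in the mother, 0.43 ± 0.01 in progeny 2, 0.48 ± 0.02 in progeny 3 and 0.44 ± 0.03 in progeny 6. The father and the other 5 progeny lay between -0.00 and 0.01. A further 5 gains, of 10 to 14 probes on chromosomes 3, 5, 6, 9 and 15, were carried by the mother and progeny 5 alone, with means over both mice of 0.29 to 0.40. At these 5 the other mice were not all at 0: at 50960874 on chromosome 9 the father measured 0.20 ± 0.14, and at 64770913 on chromosome 15 progeny 6 measured 0.21 ± 0.05. The other mice also kept a similar order over the 5 gains. Progeny 6 lay between 0.07 and 0.21, progeny 4 between -0.08 and -0.01 and progeny 7 between -0.10 and 0.03. Whether these 5 were inherited or reflect a trend over probes shared between mice was not tested. A gain of 10 probes on chromosome 4 (143338734 to 143339666) measured 0.27 ± 0.06 in the mother, 0.27 ± 0.07 in progeny 7 and 0.26 ± 0.08 in progeny 8, with progeny 5 and 6 just under the limit of size at 0.23 and 0.21. The father and progeny 1 to 4 lay between -0.01 and 0.04 there. The mother and progeny 5 to 8 thus stood apart from the other mice, as at the 3 maternal regions described next.

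**Figure D3:**
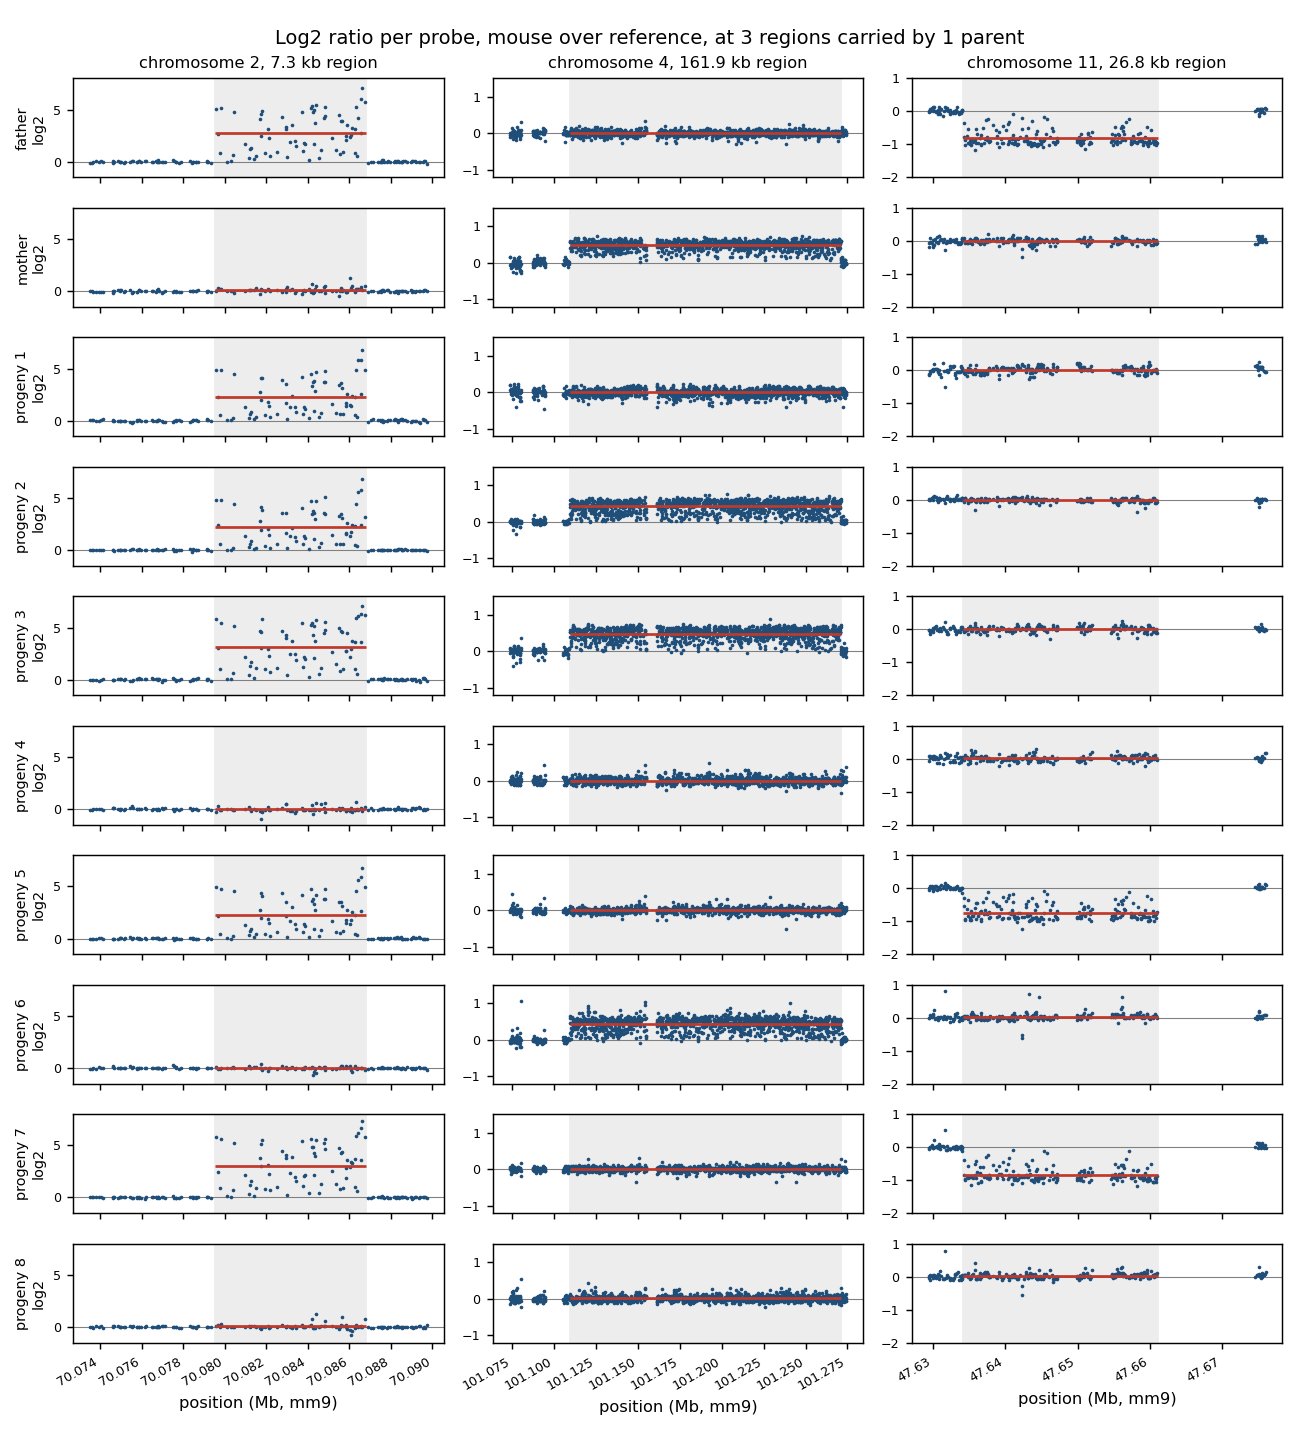
Log2 ratio of each probe (points), mouse over reference, along 3 regions carried by 1 parent, with a row for each of the 10 mice and position in Mb of mm9 on the horizontal axis. Grey marks the region and the red line its mean; the gain on chromosome 4 is raised in the mother and progeny 2, 3 and 6 across 162 kb, and the loss on chromosome 11 is lowered in the father and progeny 5 and 7 across 26.8 kb.

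Another 3 maternal regions had the same carriers, the mother and progeny 5, 6, 7 and 8. They were a loss of 39.8 kb over 149 probes on chromosome 3 (25416456 to 25456288), at -1.98 to -1.85 in these 5 mice, and gains of 107 probes on chromosome 8 (102186980 to 102205946) and 33 probes on chromosome 10 (52261676 to 52265658), at 0.27 to 0.30. The other 5 mice lay between -0.01 and 0.06 at all 3. These 5 mice were also the ones that differed from the male reference on the sex chromosomes. At the 48 X probes the mother had a median of 0.90 and progeny 5 to 8 had medians of 0.90, 0.92, 0.94 and 0.95, against medians between -0.01 and 0.01 in the father and progeny 1 to 4. At the 3 Y probes they lay between -3.38 and -2.42, against -0.02 to 0.06. The mother is female and the reference male, so that the X and Y probes fix the direction of the ratio; the labels do not give the sex of the progeny. With all called stretches of 3 or more probes, 45 regions on 18 chromosomes had exactly these 5 carriers, and 36 of their 37 losses had cores of 1 to 3 probes. The number of such regions was 29 with 5 or more probes, 25 at a log2 ratio of 0.4, 22 with only the mouse in Cy3 and 20 with each probe less its median over the mice.

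All 10 mice shared losses against the reference on chromosomes 14 and 15. The loss on chromosome 15 covered 25.8 kb and 226 probes (8343121 to 8368960) and measured -0.54 ± 0.03 (SD, n = 10), with a range of -0.57 to -0.50. On chromosome 14 a loss over 308 probes (53661805 to 53991232) measured -0.29 ± 0.03 (SD, n = 10), and one over 10 probes from 53409666 to 53525261 measured -0.29 ± 0.04 (SD, n = 10). Losses of 9 and 18 probes at 54080352 and 54216993 had means over their carriers of -0.29 and -0.30 and missed the size limits in 2 and 3 of the progeny. With 1 reference, a change in the reference mouse and one in all 10 mice give the same ratios. Which genes lie at the losses on chromosome 14 was not examined here, and whether they reflect a loss in only some of the cells of the tail, in a share that differs between DNA samples, was not tested.

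Progeny-only regions were the question of the series, and most of them were short gains in 2 mice. With all called stretches of 3 or more probes, 648 regions were carried by progeny and neither parent, 612 of them gains. Progeny 6 carried 565 of the 648 and was the sole carrier of 359. Progeny 6 or progeny 8 carried 588, leaving 60 in which neither took part. The median core of these regions held 3 probes. Those with the largest ratios had cores of 1 to 3 probes, such as a gain at 25521141 to 25521214 on chromosome 6 that measured 1.15 in progeny 6 and 0.68 in progeny 8, one at 85287205 to 85287275 on chromosome 17 that measured 1.12 and 0.67, and a probe at 137105891 on chromosome 3 that was lower in progeny 3 and 7, at -1.06 and -1.10, and higher in the father, at 0.71. Both progeny-only regions of 10 probes were gains of progeny 6, at 6222678 to 6224463 on chromosome 9 (0.28 ± 0.00) and at 73080509 to 73081822 on chromosome 17 (0.30 ± 0.01). Progeny 8 measured 0.21 ± 0.16 and 0.19 ± 0.12 there. A gain of 68 probes on chromosome 11 (3085191 to 3099912) was carried by progeny 5 and 8, at 0.41 ± 0.21 and 0.42 ± 0.16. Progeny 6 and progeny 1 also passed the limit on the mean, at 0.32 ± 0.20 and 0.25 ± 0.23. With the mouse in Cy3 they measured 0.115 and 0.023, under the limit for each orientation, and so did not count as carriers. Both parents measured 0.24 and progeny 2 measured -0.06 ± 0.19. Without progeny 6 and progeny 8, 71 progeny-only regions were called, and without progeny 6 alone 171.

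Across all called stretches the 10 mice gave 1270 aberrant regions, 980 gains and 290 losses, from 2061 calls of which 1676 had 3 probes. On the differences between orientations, less their median over the mice, the caller returned 316 false calls without the rule on orientations. As a filter on these calls, 5 or more probes left 237, against 11 false ones. With the caller itself run with at least 5 probes there were 488 regions and 63 false calls. Besides the 648 progeny-only regions, 414 were carried by progeny without separating from a parent, 188 by 1 parent, 11 by both parents and 7 by all 10 mice, and 2 had no carrier over their core. Of the 188, the father carried 56 and the mother 132. At 49 of the 188 no progeny carried the region and at 1, the chromosome 4 loss, all 8 did. These 50 passed the two-sided exact binomial test against even transmission (p = 0.00781, Benjamini-Hochberg adjusted p = 0.0294), the smallest that 8 progeny allow. The parents had 27 (father) and 28 (mother) false calls, 1 and 2 of them with 5 or more probes, and a false call in a parent would also be carried by no progeny, so that the test does not separate the 49 from false calls. The 49 had 2 to 4 probes; the largest was a loss at 86410200 to 86410657 on chromosome 9, at -0.58 in the father and -0.08 to 0.01 in the progeny, where the probe at 86410200 set the loss. Among the 14 long regions carried by 1 parent, none passed after adjustment. The smallest raw exact binomial p was again 0.00781, for the chromosome 4 loss in 8 of 8 progeny, with an adjusted p of 0.109. Over 14 tests, 1 such region alone cannot pass. The test also presumes a change on 1 of the 2 chromosome copies of the parent. A parent with the change on both copies would pass it to all progeny, so that 8 of 8 need not be a departure from even transmission. The 11 regions carried by both parents had cores of 3 probes or fewer. They included a gain at 97112448 to 97112551 on chromosome 10, at 0.33 in the father, 0.34 in the mother and 0.24 to 0.39 in the progeny.

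**Figure D4:**
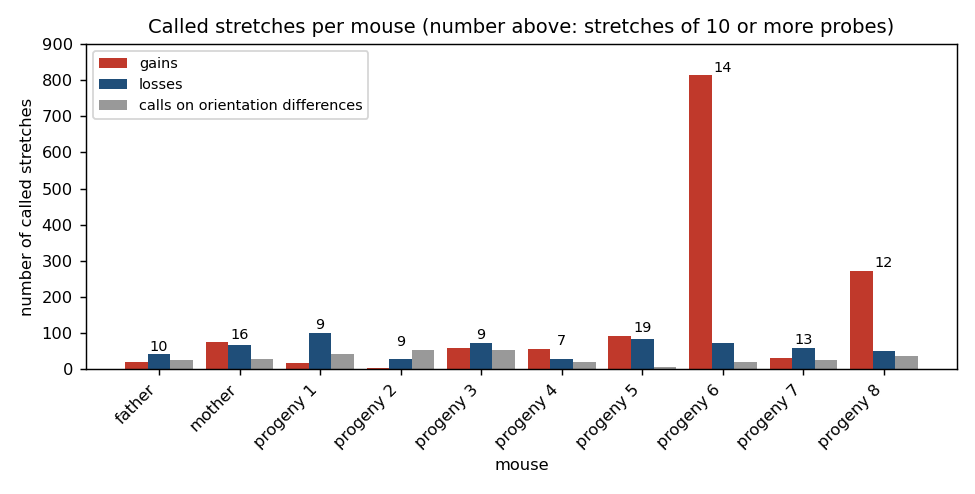
Number of called stretches per mouse, as gains (red), losses (blue) and false calls on differences between dye orientations, made without the rule on orientations (grey), with the number of stretches of 10 or more probes above the bars. Progeny 6 had 813 gains and progeny 8 had 273, against 5 to 93 in the other 8 mice, while calls of 10 or more probes among them numbered 7 to 19 in every mouse; with the caller run with at least 10 probes, progeny 6 had 63 and the others 8 to 32.

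A difference between progeny and parents in the number of called stretches was not detected. The 8 progeny had 232 ± 278 (SD, n = 8) and the parents 103 ± 58.0 (SD, n = 2), a difference of 128.9 (two-sided exact permutation p = 0.533, where the smallest possible is 0.0222). Progeny 6, with 886 calls, and progeny 8, with 324, set the mean of the progeny. Without these 2 mice the difference was 4.5 (exact permutation p = 0.857). It was 2.88 (exact permutation p = 0.933) with the caller run with at least 10 probes, and -1.5 (exact permutation p = 0.667) when only the calls of 10 or more probes were counted.

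Probe by probe, the progeny mean was set against the reference. limma found 1408 of 155044 probes past an adjusted p of 0.05, 122 higher and 1286 lower. The spread in this test comes from the 8 progeny and leaves out that of the 1 reference mouse. A change in the reference alone would therefore pass as well. Of the 1408, 279 lay in the paternal loss on chromosome 4, 224 in the loss on chromosome 15 and 414 in the losses on chromosome 14. Another 455 of them, 32.3%, lay outside all of the long regions, with a median absolute log2 ratio of 0.11. The 5 largest decreases were all on chromosome 15, led by the probe at 8343121 (-0.74 ± 0.02, SE, adjusted p = 3.21e-08). With normexp, the one at 8352247 went from -0.66 to -0.07 and no longer passed (adjusted p = 0.186), and the one at 8357864 went from -0.69 to -0.38. The largest increase was at 1 probe on chromosome 13, at 95707465 to 95707524 (1.84 ± 0.04, SE, adjusted p = 1.40e-08), and the next 4 lay between 3093370 and 3094040 on chromosome 11 (0.43 to 0.46). With only the arrays that had the mouse in Cy3, 3 of these 4 no longer passed, at 0.12 for 3093370 (adjusted p = 0.167), 0.13 for 3093605 (adjusted p = 0.0664) and -0.00 for 3093668 (adjusted p = 0.980). The probe at 3093370 also did not pass without progeny 3, 4, 5, 6 or 7 (adjusted p between 0.0580 and 0.0991). The count was 60573 with only the arrays that had the mouse in Cy5 and 76216 with only those in Cy3, and 2343 without progeny 8. The 122 higher probes numbered 81, 73, 36, 45 and 68 without progeny 3, 4, 5, 6 and 7 in turn, and 275 with loess.

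Progeny and parents did not separate at any probe past the adjusted threshold. limma gave 0 of 155044 probes past an adjusted p of 0.05, with 12044 at an unadjusted p under 0.05. In simulated data with independent noise, which the arrays do not have, it recovered 6 of 67 probes changed by 0.1. The parents shared a slide with no progeny, and with slide as a random block the count was also 0; with only the arrays that had the mouse in Cy3 it was 11. Father and mother differed at 240 probes by limma, all lower in the father, and 237 of them lay in the chromosome 4 loss. The other 3 included the probe at 86410200 on chromosome 9 (-1.65 ± 0.11, SE, adjusted p = 8.61e-05), which measured -0.35 with only the arrays that had the mouse in Cy5. In this test each parent is 1 mouse and the spread comes from the progeny alone. A region carried by some of the progeny therefore has a large spread, and no probe passed in the chromosome 2 gain (2.77 in the father, 0.12 in the mother), the chromosome 3 loss (-0.01 and -1.92) or the chromosome 11 loss (-0.82 and -0.01). The count, its direction and the share in the chromosome 4 loss, which all 8 progeny carry, thus follow from the design and do not measure how far the parents differ.

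The correlation of orientations was compared inside and outside called stretches. Across all autosomal probes the Pearson correlation of a mouse's 2 orientations had a median of 0.116 over the 10 mice and ranged from -0.249 to 0.227, and the Spearman median was -0.260. Over the 3082 probes in called stretches of 10 or more probes the median Pearson r was 0.924, with the lowest value, 0.535, in progeny 4, and over probes in no call it was -0.305. Calls needed the same sign in both orientations, so this contrast follows in part from the rule for calls. Different mice on arrays of the same orientation correlated with a median r of 0.510 with the mouse in Cy5 and 0.543 in Cy3, and no pair was below 0.0709. With both orientations averaged, the median r between mice was 0.378. It ranged from -0.194 for progeny 1 and 8 to 0.707 for progeny 5 and 7. These correlations run across probes, which are not independent replicates.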

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

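The tests of explanations in this part were all chosen after the results were seen. Among 75 sets of 8 progeny values examined, 8 had a mouse far from the other progeny. Chance would give about 3.75 for independent sets of values picked without regard to the mice. Most sets are regions picked because some of the mice were called there, and some overlap, so that the 8 cannot be set against 3.75.

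Progeny 6 stood apart by its calls, 886 against 33 to 324 in the other progeny, of which 813 were gains against 5 to 273, although with only the mouse in Cy5 progeny 1 had most calls, 1236 against 694 in progeny 6. For progeny 6 the slide is argued against, since progeny 5 from the same slide had a median of 0.038 at the 807 short gains of progeny 6. Gains private to this mouse are also argued against, since progeny 8 had a median of 0.19 at the 357 gains that progeny 6 alone carried. The called probes were dim, at a median of -1.06 relative to the array in the reference channel, but an intensity trend is argued against as the whole cause, as progeny 6 had 830 calls with loess. Removing the first principal component of the other 9 mice left progeny 6 with 750 calls. It brought progeny 8 from 324 to 109, within the 33 to 177 of progeny 1 to 5 and 7. A trend shared between mice may therefore account for the short gains of progeny 8. However, progeny 6 is one of those 9 mice, and it had a median of 0.43 at the 269 short gains of progeny 8, against 0.30 in progeny 8. The removal thus cannot tell a trend over probes from gains that these 2 mice share. For progeny 6 the removal cannot decide, since a component of the other mice need not hold a trend that is strongest in progeny 6. At the 807 short gains the other 9 mice had medians from -0.10 in progeny 1 to 0.21 in progeny 8. At the 269 short gains of progeny 8, progeny 7 from the same slide had a median of 0.14. The parents and progeny 1 to 5 had medians of -0.15 to 0.11 there, so that a part of the slide stays open for progeny 8. What sets progeny 6 apart stays open, and no biological explanation was tested.

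Progeny 8 lay far below the other progeny at 5 regions. On chromosome 14 it measured -0.40 at 53409666 (others -0.29 to -0.26), -0.36 at 53661805 (others -0.30 to -0.26), -0.45 at 54211971 (others -0.33 to -0.25) and -0.41 at 54216993 (others -0.30 to -0.24). On chromosome 6 it measured -0.25 over 10 probes from 41253635 to 41254311, where the other progeny lay between -0.04 and 0.08 and both parents at -0.01. At 2 other losses in this stretch of chromosome 14 progeny 8 was not lowest, at -0.27 from 54078604 and -0.26 from 54080352. The 4 regions on chromosome 14 lie within 1 stretch and are not independent. Which genes lie at these 5 regions was not examined here, and whether the losses reflect a loss in only some of the cells of the tail, in a share that differs between DNA samples, was not tested. Progeny 5 stood apart at the short gain on chromosome 3 from 78511756, at 0.41 against -0.07 to 0.14, and the mother measured 0.38 there.

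The carriers of the chromosome 2 gain fell on ratios of about 2.19 to 2.28 (progeny 1, 2 and 5) and 2.77 to 3.10 (father, progeny 3 and 7). A difference in copies between carriers is argued against: the mouse channel of progeny 3, with the highest ratio, lay -0.17 from that of progeny 2, with the lowest. Mouse-channel signals of the 6 carriers spanned 0.18, while the reference channel spanned 1.09, which is consistent with a reference near background whose level differs between arrays; it was -2.72 to -2.66 on slide 2 and -3.92 to -3.68 on slide 5. Presence of the sequence on 1 chromosome copy of the father, and its absence from the mother and the reference, stays open as a biological explanation for carriage by 5 of 8 progeny (exact binomial p = 0.727).

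The mother and progeny 5 to 8 were the exact carriers of 45 regions on 18 chromosomes, 37 losses and 8 gains, a number that was 14 to 29 under 6 alternatives, 3 and 5 under the 2 with 10 or more probes, and 41 to 63 under the others with all 10 mice. Chance transmission is argued against, as 0.516 regions with exactly these progeny would be expected among the mother's 132. Of the 46 maternal regions with exactly 4 carrier progeny, 97.8% had these 4, which are also the progeny high on X and low on Y. Probes that are placed on autosomes and also measure X or Y sequence may therefore account for them, with losses (median -0.93) lying between 0 and the Y probes and gains (median 0.38) between 0 and the X probes. No sequence was matched here, so copies of these sequences on X or Y were not examined.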

How the results depend on the processing

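The alternatives named here as added were chosen after seeing the data; the others were fixed beforehand. A count is called moved when it changed by more than 1.5 times. Correlations and the X difference stayed when they changed by less than the spread of the mice. The difference in calls per mouse stayed when its sign and the side of 0.05 of its exact permutation p were kept, whatever its size. It thus counts as stayed at 2.88 with the caller run with 10 or more probes and at 4.5 without progeny 6 and 8, against 128.9. Of the values under alternatives for the main results, 155 stayed by these rules, 60 moved and 4 reversed. Of those for named regions and probes, 555 stayed, 142 moved, 16 no longer passed the adjusted threshold and 3 reversed. A named probe stayed when its sign and an adjusted p under 0.05 were kept, whatever its size. The cause was not tested except where the alternative itself removes calls, probes or mice.

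Scaling and probes left the number of regions and of progeny-only regions within 1.5 times. With normexp, regions of both parents fell from 11 to 4, false calls from 316 to 74, the median correlation of orientations turned from 0.116 to -0.212, and the X difference of mother and father rose from 0.911 to 1.02. With loess, regions of both parents were 4. With each probe less its median over the mice, regions of both parents and of all 10 mice were 0 and 0, which the subtraction itself produces for shared changes, and the correlation was -0.126. With only probes well above background, regions of both parents were 7, false calls 83 and the correlation -0.00872.

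Stricter limits lowered the counts by their construction. With 5 or more probes there were 488 regions, 219 progeny-only, 77 of 1 parent, 2 of both parents and 63 false calls. With a log2 ratio of 0.4 there were 433, 184, 57 and 2, with 4 of all 10 mice and 50 false calls. With a gap of 500 kb, 4 regions were of all 10 mice. With reciprocal overlap, 18 were of both parents and 12 of all 10 mice, and with no rule on orientations 17 were of both parents.

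With only the mouse in Cy5 there were 2628 regions, 445 of 1 parent, 119 of both parents and 20 of all 10 mice, and limma gave 60573 probes for progeny against reference. With only the mouse in Cy3, 451 were of 1 parent, 67 of both parents and 23 of all 10 mice, the X difference was 0.859, and limma gave 76216 probes for progeny against reference and 11 for progeny against parents. A bias of the dyes is shared by all arrays of one orientation and cancels only in the mean of both.

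Among the added alternatives, keeping only called stretches of 10 or more probes gave 25 regions, 2 progeny-only, 14 of 1 parent, 2 of both parents, 3 of all 10 mice and 0 false calls, and the difference in calls per mouse turned to -1.5. The caller run with 10 or more probes gave 90, 19, 21, 3 and 3, with 3 false calls. The rest of the 90 did not separate from a parent or had no carrier over their core. By the limits of size, carriage by a parent thus held for most of the 25 regions and not of the 90, and the cause was not tested. The 14 of 1 parent include 3 carried by the mother and progeny 5 to 8 and 5 by the mother and progeny 5 alone. Carriage by these limits therefore does not settle inheritance. With the median rule there were 750, 416, 110, 6 and 4, with 92 false calls. Without progeny 6 and 8 there were 515 regions, 71 progeny-only. With the first principal component of all 10 mice removed, 375 were progeny-only and 7 of both parents, with 657 calls in progeny 6 and 64 in progeny 8. The calls of progeny 3 rose from 134 to 270 and those of progeny 1 fell from 120 to 19.

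Leaving out each progeny mouse gave 171 to 647 progeny-only regions, the lowest without progeny 6, and 7 to 7 of all 10 mice. limma gave 1086 to 2343 probes for progeny against reference, the highest without progeny 8, and 0 to 0 for progeny against parents. Runs of 10 probes gave 485 of 14298 for progeny against reference and 29 of 14298 for father against mother. Probe by probe these were 1408 and 240 of 155044, so that the counts fell with runs while the shares rose.

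Named values reversed in 3 cases. The probe at 3093668 on chromosome 11 gave -0.0027 for progeny against reference with only the mouse in Cy3. The probe at 84391201 on chromosome 9 gave 0.16 for father against mother with only the mouse in Cy5. The gain from 137107248 on chromosome 3 gave -0.025 with normexp. The planned use of gene lists with regions of 10 or more probes was not run, since no list was tested. Signal over background, 13.8 to 23.9 at the median, limits the ratios of dim probes, as at the chromosome 2 gain.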
